A study of Caenorhabditis elegans with 2 samples.

How the data were processed

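Per the labels, chromatin of whole L1 larvae of a strain stably carrying SOX-4 with a C-terminal GFP-FLAG tag was sheared by sonication and precipitated with an anti-GFP antibody, in 2 biological replicates of 1 group. The authors deposited, per the file notes, 1 list of regions for each replicate and 1 for both replicates' alignments together, each called with a control alignment, and an optimal list derived from these by the irreproducible discovery rate (IDR). Each of the first 3 lists holds 30000 regions and includes background, so it is not a list of significant peaks. The peak caller, its version and the IDR threshold are not given in the sources used here. The labels name a possible control experiment, which was not analysed here.

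The authors' deposited signal per region, in the narrowPeak signal column, was used only to rank and describe regions within a list. The deposited −log10 q-value reached its highest value at 488 of the optimal peaks and was used only to describe the lists. All lists were deposited on ce10 and ce11. Coordinates are given on ce11, 1-based, without conversion between builds, and the ce10 lists were used only for counts, widths, signal and replicate overlap. Read depth is unknown, so intervals on shares cover the counting of regions or genes only.

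Gene positions came from Ensembl release 115 for assembly WBcel235, whose sequence is that of ce11, and sequence from the RefSeq copy of that assembly. Every region ended within the length of its chromosome. Of 46926 annotated genes, 44750 matched a RefSeq symbol by WormBase identifier (WormBase release 298), and the others kept the Ensembl name. RefSeq symbols were taken after a first look at the data, because Ensembl names some microRNA genes differently. Pseudogenes were left out, which left 44798 genes, 15363 of them piRNA genes. A gene was assigned each peak whose summit lay from 1000 bp upstream to 200 bp downstream of its 5′ end, so a peak between divergent genes counts for both, as 313 optimal peaks did for coding genes. By this rule 1133 coding genes had an optimal peak and 7543 a candidate.

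Locations, chromosomes and gene lists were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The background was the other regions of the pooled list, or genes with at least 1 candidate in the window. Protein-coding lists were tested among coding genes and lists of RNA genes among all genes. Motifs were sought on both strands within 50 bp of the summit. Regions and genes are not biological replicates, so these p-values describe the lists and not variation between animals. Replicate overlap was compared with 1000 random placements, and permutation tests used 100000 resamples. Shares have exact (Clopper-Pearson) 95% intervals, and a count of 0 is given the upper limit of that interval.

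The tests, 30 gene lists, 9 motifs and the rule for named genes were fixed before the data were examined. The rule names the genes at the 25 strongest optimal peaks, up to 4 members of each list with the strongest promoter peak, and sox-4, unc-119 and the Sox genes whatever their values. A result that this rule names among the chemoreceptor genes is not reported here. Alternatives covered stricter peaks, other windows, overlaps, backgrounds, gene assignment, motif windows and flanks, the ce10 lists, and each replicate's own 1497 strongest regions in place of the optimal list. Those added later left out chromosome X, the surroundings of sox-4, piRNA genes or mitochondrial regions (in overlaps and in ranks), used Ensembl symbols, compared locations outside promoter windows, or stratified by GC content, for ACAAT too.

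The procedures were tested on simulated data first. For the promoter comparison over 30000 regions, a planted odds ratio of 3 was recovered as 3.09 ± 0.179 (SD, 100 simulations), and 4 of 100 simulations with no difference passed the threshold. For gene lists over 7543 genes, a list planted at an odds ratio of 4 was called in 100 of 100 simulations, and 0.379% of lists with no difference were called. Each simulated list held 100 genes with a candidate, and peaks were given to genes independently. Most lists tested here had fewer such genes, and neighbouring genes can share a peak, so these rates do not carry over to them. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.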

Results

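Chromatin precipitated with tagged SOX-4, a Sox-family transcription factor with an HMG-box DNA-binding domain, was profiled by ChIP-seq in whole first-stage (L1) Caenorhabditis elegans hermaphrodite larvae. No sample without the tagged protein was analysed here, so whether the peaks need SOX-4 stays open. The animals carried a transgene for SOX-4 fused to GFP, were hatched without food after bleaching, and were collected 6 hours after synchronization for immunoprecipitation with an anti-GFP antibody. The labels give 1 group of 2 biological replicates and no second condition, so the only comparison between samples was replicate 1 against replicate 2. All other comparisons set the authors' optimal peaks against the remaining regions of the same candidate list. Read depth is unknown, since the lists give regions and no read counts.

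The optimal list held 1497 peaks on ce11, which were the 1497 regions of highest signal among 30000 candidates called on both replicates together. Their median width was 396 bp, and they covered 0.530% of the nuclear genome. Signal, the authors' own value for each peak, ran from 51.3 to 550.1 with a median of 76.2. On ce10 the optimal list held 1486 peaks with a median width of 396 bp and a median signal of 76.5. Peaks of equal rank in both builds differed in signal by at most 1.04%.

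Of the 25 strongest peaks, 12 were on X, 10 of them outside promoter windows. The peak of highest signal (550.1) was intergenic, at X from 13700590 to 13701040, 6047 bp from the 5′ end of the nearest coding gene, K02D3.1. It ranked 1 in replicate 1 and 14 in replicate 2, where its signal was 246.0. Mitochondrial regions took the 10 highest ranks of replicate 2, and peaks with a signal of 275.4, 257.5 and 247.6 there also lay above it. The next (500.8; I from 4172017 to 4172359) had its summit 36 bp upstream of sls-2.4, which encodes an SL2 trans-spliced leader RNA, and 581 bp upstream of the coding gene egg-5. A peak of signal 370.3 on chromosome II, from 5844671 to 5845000, lay 38 bp upstream of sls-2.1, another spliced-leader gene. The noncoding gene linc-128 on V held a peak of signal 487.6, from 1151322 to 1151679.

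Among the 25 strongest peaks, 12 had their summit in a promoter window. Ribosomal protein genes at these were rpl-3 (signal 466.2), rpl-35 (347.0) and rpl-18A (346.6). The promoter of tasp-1 held a peak of signal 465.3, that of wbp-4 and F56G4.6 one of 431.6, and that of akap-17A, lig-4 and C07H6.2 one of 428.3. The promoters of nhl-2 and tag-340 shared a peak of 361.5. A peak of 361.5 in the promoter of C47E8.4 had its summit within hsp-90, the cytosolic Hsp90 chaperone gene. On X, peaks of 462.1 and 456.5 were in introns of Y41G9A.17 and of mom-1, a Porcupine-family gene needed for Wnt secretion. The peak at C18A11.13 (453.4) lay 4895 bp from the 5′ end of xol-1, the sex-determination switch gene.

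The same regions ranked high in both replicates. Of the 1497 strongest regions of replicate 1, 1014 (67.7%) overlapped the 1497 strongest of replicate 2 by at least 1 bp. Random placement of the replicate 2 regions along their chromosomes gave 1.14% on average and at most 2.07% (permutation p = 0.001, the smallest that 1000 shuffles can give). Random placement is a low baseline, since background regions recurred too. Of all 30000 regions of replicate 1, 13764 (45.9%) overlapped some region of replicate 2. That share comes from longer lists, so it is not a direct baseline for the 67.7%. All 25 of the strongest optimal peaks were in both replicates' top lists, with ranks no lower than 28 in replicate 1 and 46 in replicate 2. These peaks were selected on signal in the same 2 replicates together, so their high ranks in each are partly set by that selection.

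Of the optimal peaks, 978 of 1497 (65.3%) overlapped both top lists, among them all 100 of the strongest and 6 of the 100 weakest. All 3 lists end at rank 1497, so low overlap among the weakest is largely set by where the lists end. High overlap among the strongest is partly set by their selection on the pooled signal. Across the 1493 optimal peaks with a region in both replicates' lists, Pearson's r of log2 signal was 0.71 and Spearman's rho 0.61. Each had a permutation p of 1e-05, the smallest that 100000 resamples can give, for 2 coefficients of 1 comparison. These coefficients are across regions, which are not independent replicates, and the regions were selected on signal in the pooled data. Each peak was given the signal of the strongest region it overlapped in each replicate, so some neighbouring peaks carry the same values.

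**Figure D1:**
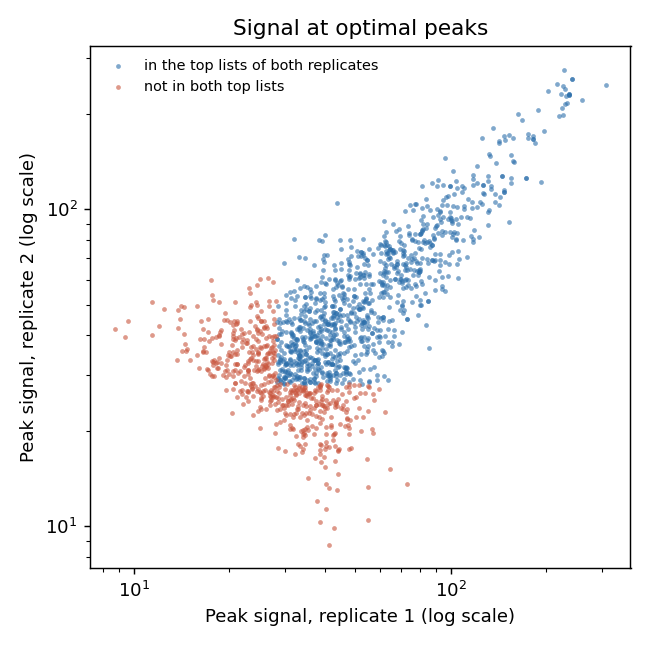
Signal of the strongest region that each optimal peak overlaps in replicate 1 (x axis, log scale) and in replicate 2 (y axis, log scale), in the authors' units. Each point is 1 peak, blue where it overlapped the 1497 strongest regions of both replicates and red where it did not, and Spearman's rho over the 1493 points is 0.61.

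SOX-4-eGFP peaks were concentrated at gene 5′ ends. Promoter windows, from 1000 bp upstream to 200 bp downstream of an annotated gene 5′ end, held 1005 of 1497 optimal summits (67.1%, exact 95% interval 64.7 to 69.5). They held 11492 of 28503 other candidates (40.3%; 39.7 to 40.9), an odds ratio of 3.02 (Fisher's exact test, two-sided, p = 2.7e-92). With protein-coding genes alone the shares were 54.4% and 25.02%. The median distance from an optimal summit to the nearest coding 5′ end was 562 bp.

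Other locations held smaller shares of optimal peaks than of other candidates, and since shares sum to a whole, the larger promoter share lowers them together. Introns held 14.7% of optimal summits against 27.3% of other candidates (adjusted exact p = 1.3e-29), and coding exons or 5′ UTRs 1.54% against 8.996% (adjusted exact p = 1.3e-32). The 3′ UTRs held 0.468% against 2.70% (adjusted exact p = 4.6e-10), and intergenic sequence 15.4% against 19.6% (adjusted exact p = 6.7e-05). Noncoding genes held 0.735% against 1.08%, which was not past the threshold (adjusted exact p = 0.24). All are Fisher's exact tests with Benjamini-Hochberg adjustment over 6 locations. Among the 492 optimal peaks and 17011 other candidates outside promoter windows, a comparison chosen after the data were seen, exons and 3′ UTRs still held fewer optimal peaks. Coding exons or 5′ UTRs had 4.67% against 15.1% (adjusted exact p = 3.1e-12) and 3′ UTRs 1.42% against 4.53% (adjusted exact p = 0.00054). Introns had 44.7% against 45.8%, not past the threshold (adjusted exact p = 0.68). Intergenic sequence turned the other way, with 46.95% against 32.8% (odds ratio 1.81, adjusted exact p = 3.9e-10). These tests were adjusted over 5 locations.

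**Figure D2:**
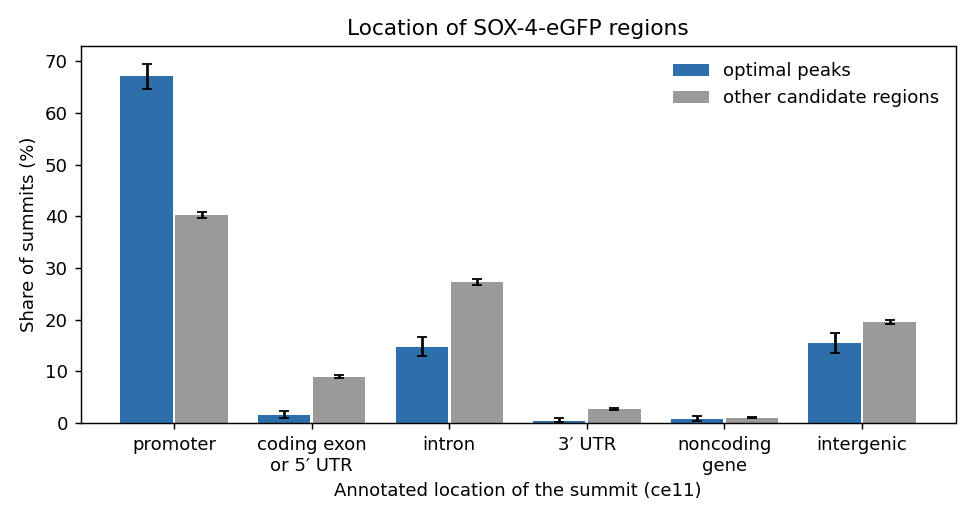
Share of summits (y axis, %) in each annotated location (x axis) for 1497 optimal peaks (blue) and 28503 other candidate regions (grey), with exact 95% binomial intervals as error bars. Promoter windows held 67.1% of optimal summits and 40.3% of the others.

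Peaks at promoters also had the higher median signal. The share in promoter windows was 73.8% among the 748 strongest peaks, but 12 of 25 at the very top. Median signal was 80.3 at the 1005 promoter peaks and 69.7 at the other 492, a difference of 0.20 on the log2 scale (permutation test, two-sided, p = 1e-05, the smallest possible). On X the pattern of location differed from that of the autosomes: 175 of 315 X peaks (55.6%) were in promoter windows against 830 of 1182 autosomal peaks (70.2%; odds ratio 0.530, Fisher's exact p = 1.5e-06). The same split among other candidates was 36.4% against 41.3% (odds ratio 0.816, exact p = 2.6e-11).

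Chromosomes II and III held more optimal peaks than the other candidates would give, and IV and V fewer. Chromosome II had 14.4% of optimal peaks and 11.1% of other candidates (adjusted exact p = 0.00047), and III 16.3% and 14.2% (adjusted exact p = 0.044). Chromosome IV had 15.2% and 20.6% (adjusted exact p = 1.1e-06), and V 17.3% and 19.6% (adjusted exact p = 0.044). X had 21.04% and 19.8% and I 15.8% and 14.7%, neither past the threshold (both adjusted exact p = 0.25). Fisher's exact tests were adjusted over 6 chromosomes. The call for III was lost without replicate 2 (odds ratio 1.10 in place of 1.17, adjusted exact p = 0.20) and that for V among the 748 strongest peaks (0.834 in place of 0.859, adjusted exact p = 0.10). Against chromosome length II was not enriched while X was (odds ratio 1.24, adjusted exact p = 0.0024).

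Ribosomal protein genes, and heat shock and chaperone genes, had optimal peaks in their promoter windows more often than other coding genes. An optimal peak lay in the promoter window of 36 of 69 ribosomal protein genes with a candidate (52.2%) against 14.7% of other coding genes (adjusted exact p = 4.8e-12). The strongest after the 3 named above was at rpl-15 (signal 316.5, 347 bp upstream). Heat shock and chaperone genes had a peak at 8 of 12 (66.7%; adjusted exact p = 0.00043). These included hsp-60, the mitochondrial chaperonin (signal 328.7), hsp-1, a cytosolic Hsp70 (199.6), hsp-110 (122.8) and the small heat shock gene sip-1 (110.7). The chaperone call was lost when each summit went to its nearest gene 5′ end alone (odds ratio 3.83 in place of 11.4, adjusted exact p = 0.37). Its odds ratio was 6.19 without replicate 1 and 13.8 without replicate 2, both past the threshold.

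Lists of snRNA and snoRNA, tRNA and microRNA genes were tested among all genes, which include 15363 piRNA genes, 78 of them with an optimal peak. Peaks lay at 74 of 263 snRNA and snoRNA genes (28.1% against 8.42% of other genes; adjusted exact p = 7.3e-19), a list that includes the spliced-leader genes sls-2.4 and sls-2.1 and the snoRNA genes T27A8.8 (signal 336.9) and C06A1.9 (321.0). Peaks lay at 70 of 351 tRNA genes (19.9% against 8.48%; adjusted exact p = 2.9e-10), led by C28G1.t1 (187.7) and R04A9.t1 (177.9), both on X. With piRNA genes left out of the background, the odds ratios fell from 4.26 to 2.41 for snRNA and snoRNA genes and from 2.69 to 1.52 for tRNA genes, both still past the threshold. Without X the tRNA odds ratio was 1.47 and not past the threshold (adjusted exact p = 0.40). MicroRNA genes had peaks at 18 of 91 (19.8% against 8.64%; adjusted exact p = 0.0050). A single peak on X of signal 155.2 counted for mir-54, mir-55 and mir-56, and mir-354 had one of 151.6. The microRNA call (odds ratio 2.61) was lost under 5 of 8 alternatives, among them leaving out piRNA genes (odds ratio 1.48, adjusted exact p = 0.50), replicate 1 (1.88, adjusted exact p = 0.11) or replicate 2 (1.97, adjusted exact p = 0.098).

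Chemoreceptor and neuropeptide genes had fewer peaks than other coding genes. Chemoreceptor genes had an optimal peak at 18 of 428 (4.21% against 15.7%; adjusted exact p = 4.3e-12), with srdf-3 (signal 120.7) and sri-5 (117.3) among them. None of the 39 neuropeptide genes with a candidate had one, which allows a share of up to 9.03%, against 15.1% of other coding genes (adjusted exact p = 0.012). From an odds ratio of 0, the neuropeptide call was lost without replicate 2 (odds ratio 0.162, adjusted exact p = 0.15), among the 748 strongest peaks (odds ratio 0, adjusted exact p = 0.20) and with the nearest 5′ end (odds ratio 0.312, adjusted exact p = 0.37). Nuclear hormone receptor genes had peaks at 10 of 127 (7.87% against 15.1%, odds ratio 0.479, adjusted exact p = 0.087). The strongest were at nhr-47 (182.2), nhr-48 (156.5), nhr-196 (84.0) and nhr-142 (77.3). This list was past the threshold without X (odds ratio 0.358, adjusted exact p = 0.025). Its odds ratio was 0.417 without replicate 1 and 0.851 without replicate 2, past the threshold in neither. All p-values for lists are from Fisher's exact tests adjusted over 30 lists.

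**Figure D3:**
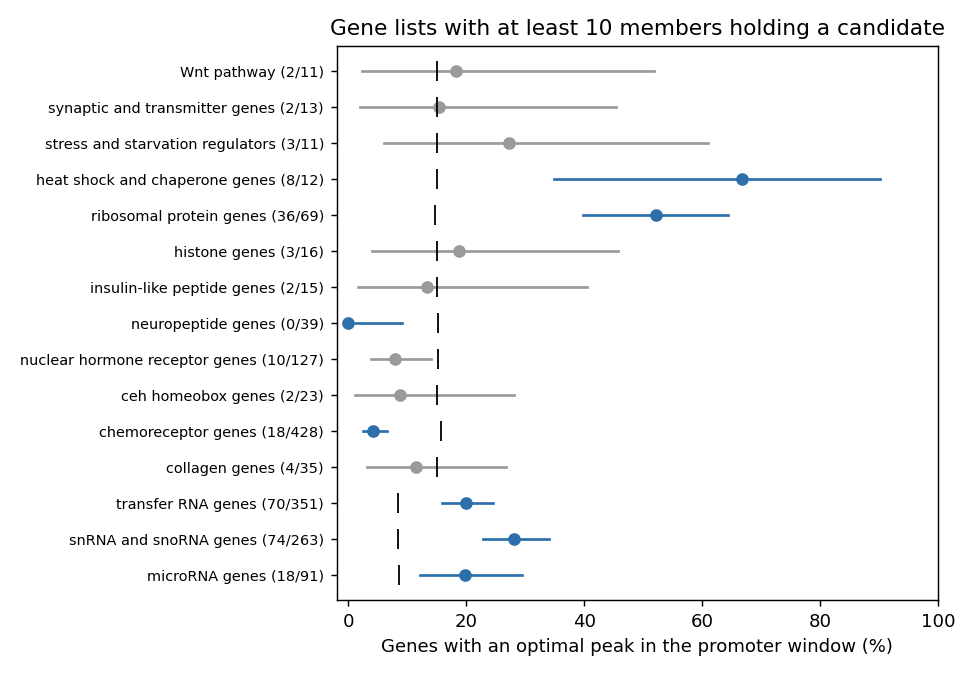
Percent of genes with an optimal peak in the promoter window (x axis) for each list with at least 10 members holding a candidate, with exact 95% intervals and counts beside the names. Blue marks lists past the threshold after adjustment, grey the rest, and the black ticks the other genes, at 15.7% for chemoreceptor genes and 8.42% for snRNA and snoRNA genes.

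None of the lists of developmental regulators or tissue genes that follow passed the threshold. With the nearest 5′ end, heterochronic genes (odds ratio 38.4, adjusted exact p = 0.0022), stress and starvation regulators (6.01, adjusted exact p = 0.022) and collagen genes (0, adjusted exact p = 0.04996) did. Wnt pathway genes had peaks at 2 of 11, at mig-5, a Dishevelled gene (signal 206.8), and wrm-1, a beta-catenin gene (198.5). Stress and starvation regulators had peaks at 3 of 11, namely hif-1 (123.5), hlh-30 (59.99) and atfs-1 (52.2). The atfs-1 peak ranked 7392 in replicate 1 and 1055 in replicate 2, and the hlh-30 peak 1015 and 3045. TGF-beta pathway genes had 1 of 8 (daf-1, 66.9), heterochronic genes 1 of 5 (lin-66, 118.8) and cuticle and molting genes 1 of 7 (dpy-8, 60.3, which ranked 15325 in replicate 1 and 489 in replicate 2). Synaptic and transmitter genes had 2 of 13, at egl-21 (59.99) and snb-1 (52.5, which ranked 1703 in replicate 1 and 2159 in replicate 2). Histone genes had 3 of 16, with his-37 at 270.1 and his-67 and his-68 sharing a peak of 60.8. Insulin-like peptide genes had 2 of 15 (ins-39, 249.8, and ins-14, 62.1), ceh homeobox genes 2 of 23 (ceh-38, 118.0, and ceh-23, 55.6) and collagen genes 4 of 35, with col-71 (116.2), col-38 (63.0), col-148 (59.0) and col-63 (53.3).

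Peaks were at 0 of 7 Notch pathway genes, 0 of 3 Hox genes and cofactors, 0 of 8 neuronal identity regulators, 0 of 1 proneural bHLH gene and 0 of 2 muscle and mesoderm regulators. They were at 0 of 4 pharynx regulators, 0 of 3 endoderm regulators and 0 of 3 epidermis and seam cell regulators. Among tissue genes they were at 0 of 9 muscle structural, 0 of 6 intestinal and 0 of 6 germline genes. A count of 0 allows a share of up to 41.0% for the Notch pathway and 33.6% for muscle structural genes. No adjusted p for these lists was under 0.05.

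Of the 5 Sox genes, sox-4 alone had an optimal peak in its promoter window. That peak (X from 3509247 to 3509642, signal 80.3) lay 439 bp upstream of the 5′ end. Its signal was 27.6 in replicate 1, where it ranked 1554 and so outside the 1497 strongest regions, and 47.6 in replicate 2, where it ranked 546. A far stronger peak (X from 3507175 to 3507596, signal 421.5, rank 15) lay in a sox-4 intron, with a signal of 203.1 in replicate 1 and 236.6 in replicate 2. An optimal peak of signal 53.3 lay within sox-2. The promoter windows of sox-2 and sox-3 held candidates of signal 34.2 and 33.5, below the optimal list, and sem-2 and egl-13 had no candidate in the window or the gene. The list as a whole, with 1 of 3, was not past the threshold (odds ratio 2.83, adjusted exact p = 1), and without replicate 2 its odds ratio was 0.

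The strain carries an integrated copy of the tagged gene, so the surroundings of sox-4 were compared with those of 19973 coding genes. Within 20 kb of sox-4 there were 6 optimal peaks, more than around 99.9% of genes, and 27 candidates, more than around 97.4%. At npr-16, the neighbouring gene, optimal peaks of signal 57.7 and 54.3 were in introns, the former without a region in the list of replicate 1. The gene unc-119, mutated in this strain, had 1 optimal peak and 18 candidates within 20 kb, more candidates than 79.3% of genes, with its strongest peak inside the gene (70.7). Within 10 kb the candidates at sox-4 exceeded those of 93.0% of genes.

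**Figure D4:**
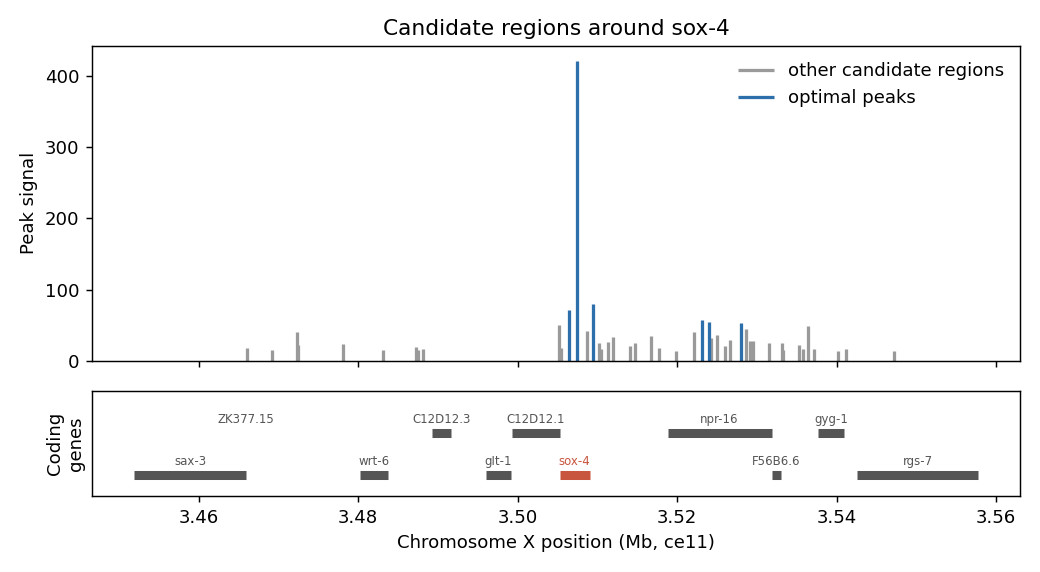
Signal (y axis) and position (x axis, Mb of X on ce11) of candidate regions within 40 kb of sox-4, as vertical lines at the summits, blue for optimal peaks and grey for other candidates, with coding genes below and sox-4 in red. The intron peak of sox-4 reaches 421.5.

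Matches to the Sox core WWCAAWG were less frequent at summits than beside them. Of 1497 optimal peaks, 167 (11.2%) had a match within 50 bp of the summit, against 15.3% in the flank 400 to 500 bp to the left (exact McNemar test, two-sided, adjusted exact p = 0.0023) and 15.1% at other candidates (Fisher's exact test, adjusted exact p = 3.1e-05). The shorter core ACAAT was at 23.2% of summits against 28.1% of flanks (adjusted exact p = 0.0057). GC content was 44.4% ± 9.55 (SD over 1497 windows) at summits, 36.1% in the flanks and 33.1% at other candidates. Compared within 10 strata of GC content, a stratification chosen after the data were seen, the odds ratio of WWCAAWG against other candidates was 0.991 (95% interval 0.836 to 1.18). For ACAAT it was 0.740 without strata and 1.11 (0.979 to 1.27) within them.

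GAGA repeats and E-boxes were enriched at summits. GAGAGA was at 19.4% of summits against 5.81% of flanks (adjusted exact p = 3.8e-28) and CACGTG at 5.41% against 1.87% (adjusted exact p = 8.6e-07). Within GC strata their odds ratios against other candidates were 1.75 (1.51 to 2.03) and 1.66 (1.29 to 2.13). CAGSTG was at 6.68% against 4.34% (adjusted exact p = 0.0092), with an odds ratio within strata of 0.979. TTTCAG was rarer at summits, 8.68% against 22.7% (adjusted exact p = 2.6e-25), and stayed lower within strata (0.608). The forkhead motif TRTTTAC was at 2.34% against 3.81% (adjusted exact p = 0.032), with an odds ratio against other candidates of 0.633 without strata and 1.04 (0.732 to 1.48) within them. TGATAA (6.55% against 7.82%; adjusted exact p = 0.22) and TGASTCA (1.67% against 1.14%; adjusted exact p = 0.28) were not past the threshold against the flank. Against other candidates both were, with odds ratios of 0.651 (Fisher's exact test, adjusted exact p = 3.4e-05) and 1.65 (adjusted exact p = 0.026). Within strata these were 1.10 (0.889 to 1.37) and 1.54 (1.01 to 2.35), and neither passed the threshold (adjusted Mantel-Haenszel values of 0.60 and 0.13). The McNemar tests were adjusted over 9 motifs.

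**Figure D5:**
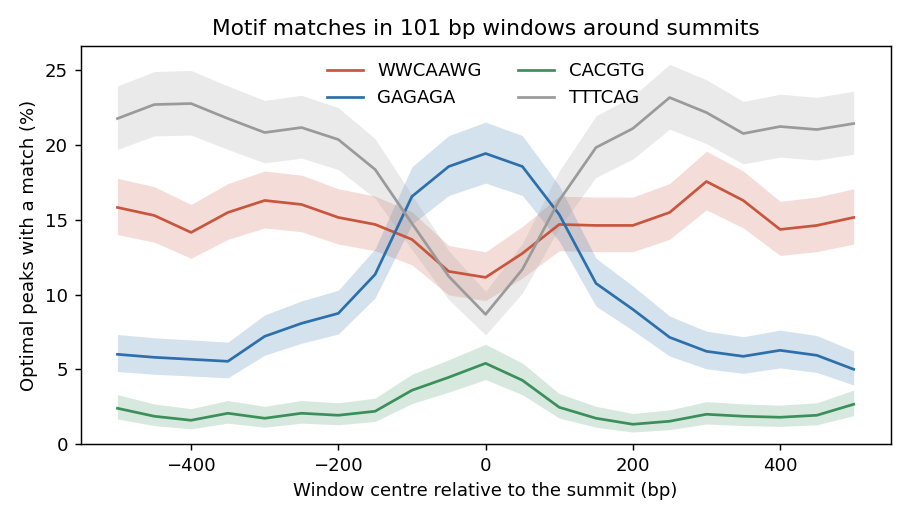
Percent of optimal peaks with a motif match (y axis) in windows reaching 50 bp either side of each distance from the summit (x axis, bp), with exact 95% intervals shaded. At the summit GAGAGA reaches 19.4% and CACGTG 5.41%, while WWCAAWG is at 11.2% and TTTCAG at 8.68%.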

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

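Regions of the mitochondrial genome appeared in the list of replicate 2, while the optimal peaks compared by gene, location and motif are all nuclear. They entered only the replicate overlap, the ranks given for replicate 2 and the alternatives in which the list of replicate 2 stood in for the optimal peaks. That list held 13 such regions, and those of replicate 1, of both replicates together and of the optimal peaks held 0. Whether mitochondrial regions were removed from some lists is not given in the sources used here, and the list called on both replicates together held 0 despite the signal in replicate 2. The counts of 0 are therefore not read as absence, nor the 13 as a difference between the replicates. They took the 10 highest ranks of replicate 2, with signal up to 6772 against 275.4 for the strongest nuclear region, and covered 23.7% of the 13794 bp mitochondrial genome. The ce10 list of replicate 2 also held 13.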

How the results depend on the processing

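The promoter, replicate, Sox flank and signal results kept their direction and side of the threshold under every alternative run on them. No alternative run on the Sox flank comparison took GC content into account. The 748 strongest optimal peaks were by construction fewer than 1497. The GC-stratified comparison, chosen after seeing the data, ended the Sox call against other candidates (0.991, interval 0.836 to 1.18), and with ACAAT the ratio passed to 1.11. Also chosen after seeing the data, the comparison outside promoters turned intergenic sequence (1.81) and noncoding genes (1.24, past the threshold in neither), and ended the call for introns (0.959). At sox-4 the percent of genes with fewer candidates was 93.0 within 10 kb, 96.9 within 40 kb and 99.5 to 99.8 with either replicate left out. The cause was not tested for these or the changes that follow. Odds ratios changed direction for chromosome X with the strongest peaks (0.926) and for II against chromosome length (0.933). Among lists, none of them past the threshold, direction changed with the strongest peaks for synaptic (0) and histone genes (0.675). Without replicate 1 and without replicate 2, the ratios of lists that changed direction in either were 3.08 and 0 for Sox, 1.23 and 0.837 for Wnt, 2.05 and 0.651 for TGF-beta, 0.615 and 0.390 for synaptic, and 1.54 and 1.17 for germline genes. Without replicate 1 alone they changed for cuticle (1.54) and muscle structural genes (1.03). It changed for histone genes against all genes (0.723). With the nearest 5′ end it changed for TGF-beta (2.88), nuclear hormone receptor (1.06) and ceh genes (1.53), and without X for TGF-beta genes (1.07). List calls were lost in 10 cases and gained in 4: heterochronic (38.4), stress and starvation (6.01) and collagen genes (0) with the nearest 5′ end, and nuclear hormone receptors without X (0.358). The other 207 without a change of direction kept their side. Ranks of the 25 strongest peaks moved by at least the replicate SD for 7 without replicate 2 and 21 without replicate 1. Without the mitochondrial regions of replicate 2, which push nuclear peaks down, the latter count was 9 (chosen after seeing the data). That SD came from the same 2 replicate ranks, so peaks whose replicates agree are more readily counted as moved. The sox-4 intron peak, of rank 15 and of rank 17 in each replicate, was counted so. These counts therefore do not measure how stable the ranks were. The Sox list without X, pharynx regulators without replicate 1 and endoderm regulators without replicate 2 gave no odds ratio. No paired analysis was possible because there is 1 group.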

Other observations

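Tests chosen after the result was seen were the first of the X-linked sites and the run count of the sox-4 surroundings, and the GC-stratified comparisons were added after the motif shares were known. The share of genes with fewer candidates than sox-4 was planned, and was set against extra copies only after its value was seen.

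Beyond the fixed motifs, GC-rich sequences led at summits. Of 2080 sequences of 6 bases, 446 were more frequent at summits than in flanks and 341 less (exact McNemar tests, adjusted over 2080). ACGCGC was at 12.5% of summits against 1.14% of flanks, and GACGCA at 14.4% against 2.14%. AAAATT was at 21.04% of summits against 42.2% of flanks. Of 5 sequences of Sox type chosen after the motif shares were seen, AACAAA, AACAAT and ACAAAG were rarer at summits, and ACAATA and ACAATG did not differ past the threshold.

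The Sox core was rarer at summits than in flanks and than at other candidates, and base composition is a candidate explanation. Within GC strata the odds ratio against other candidates was 0.991, with an interval of 0.836 to 1.18. The comparison with flanks was not stratified, so that value does not bear on it, though GC content was 44.4% at summits and 36.1% in flanks. Recruitment through Sox sites might have raised matches in the stronger peaks, yet 69 of the 748 stronger and 98 of the 749 weaker peaks had one (odds ratio 0.675, Fisher's exact p = 0.021). That bound was set without GC content, which was 46.1% in the stronger and 42.7% in the weaker peaks. Within GC strata the ratio was 0.818 (0.583 to 1.15), so the test does not decide whether Sox sites set the signal.

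Strong X peaks often carried GCGCAGGG, the core of the MEX motif, known from sites on X that recruit the dosage compensation complex. It lay within 100 bp of the summit at 17 of 315 optimal X peaks and 2 of 1182 autosomal ones, and at 11 of the 20 strongest X peaks against 0 of the 20 strongest autosomal peaks. Enrichment of such recruitment sites in the libraries is a candidate explanation that stays untested: the odds ratio against other X candidates, 64.4 (Fisher's exact p = 2.6e-18), was measured on the peaks in which the motif was noticed and only restates the pattern. Of 167 rearrangements of the core, 0 reached 17 X peaks and the highest reached 7, so other orders of these bases were rarer there. That does not decide on GC-rich sequence, since the core was noticed in these same peaks, which favours it over its rearrangements. Rearrangements also keep the counts of bases but not which bases adjoin. Whether the sites need SOX-4 stays open, because no sample without the tagged protein was analysed here.

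Candidate regions were dense around sox-4, where 97.4% of coding genes had fewer candidates within 20 kb. Extra copies of the tagged locus in the strain may add reads there, but that percentage is the pattern itself and does not bear on them. Gene density may account for the number too: 6.08% of the 839 X genes with like gene density had at least the 27 of sox-4, with a median of 16 and a highest value of 42. That comparison counted genes and candidates and not where they lay. In the list of both replicates together, no candidate had its summit between 3488060 and 3505191, where C12D12.3, glt-1 and C12D12.1 begin. The lists of the single replicates did have regions there, with summits at 3499587 in replicate 1 and 3502056 in replicate 2. The gap therefore does not show whether candidates follow gene starts. Counted as runs of summits at most 2500 bp apart, a count chosen after the density was seen, the run at sox-4 held 33 regions over 31.97 kb (X from 3505191 to 3537165) and ranked 3 of 10783 runs, but 115 of 11661 in replicate 1 and 27 of 11675 in replicate 2. Both explanations stay open, and no biological explanation was tested.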
